A study of Drosophila melanogaster with 6 samples.

How the data were processed

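RNA from the heads of adult Drosophila melanogaster males was measured on 6 Affymetrix expression arrays, 3 from males that carried the Sxlfp7BO deletion of the Sex-lethal gene (Sxl) and 3 from wild-type brothers. Per the labels' protocols the flies were 2 to 5 days old and raised at 25 °C, heads were put in TRIzol, and biotin-labelled cRNA was made by the array maker's manual. The labels call the 3 samples of each genotype biological replicates.

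The authors deposited 1 linear array intensity per probe set and array. The method of summarisation, background correction and normalization is not given in the sources used here. The 6 distributions were close to identical, with median intensities from 14.2 to 14.6, so the intensities were taken as normalized between arrays before deposit and received no further normalization. The rule for this was a difference of array medians under 0.2 on the log2 scale, and the difference was 0.04. The lowest intensity on any array was 3.52. No background level was measured, and folds of probe sets that come close to the lowest intensities in 1 genotype may be understated. Arrays have no read depth, and the number of arrays limits the precision. The median standard error of a log2 fold change was 0.08.

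All values were analysed as log2(intensity + 1) in R 4.3.3 with limma 3.58.1, so fold changes are on that scale and run from wild type to deletion. Of 18952 probe sets, 183 controls were left out, and the 11261 with a mean log2 value over all 6 arrays at or above the 40th percentile (an intensity of 8.35) were tested. The fit had genotype as its only term, with lmFit and eBayes with an intensity trend, two-sided, and p was adjusted by Benjamini-Hochberg, with a threshold of 0.05. Adjusted p below are from this limma fit. Values for Sxl, cm and ct are from the same fit without the filter.

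Gene names came from the array's platform annotation, which gave 1 gene for 13647 probe sets, several for 402 and none for 4720 of those that are not controls. Of the 13647, 13544 were updated through the Entrez identifier and 91 through the name in a table of RefSeq genes (assembly Release 6 plus ISO1 MT), and 12 kept the array's name. That table was used for names, chromosomes and the order of genes. The build behind the array's design is not given in the sources used here, so no coordinates are given, and distances are in genes from Sxl, negative on the side of cm.

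Lists of genes were fixed before the data were examined, with markers of other cells and tissues among them. Of 29 lists, 26 had the minimum of 5 measured genes. They were tested with camera at a preset inter-gene correlation of 0.01 over 8670 genes, each by its probe set with the highest mean, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Calls inside and outside the cm to ct interval were compared with Fisher's exact test, two-sided, and shifts with camera. Fisher's test takes probe sets as independent, which neighbours and probe sets of a single gene are not.

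The genes named were fixed by rule before the data were examined. They are Sxl, cm and ct, the 12 genes with the largest rise and the 12 with the largest fall among probe sets past the threshold whose 3 values in a genotype all lay beyond the 3 of the other, up to 4 members of each list with the smallest p, and up to 10 called genes of the interval. Other genes named were chosen after their values were seen.

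Equal replicate numbers were checked for pairing. Deviations from the genotype means correlated at 0.216, 0.248 and 0.114 between arrays with the same number, and from -0.223 to 0.0573 between arrays with different numbers. Every pair was above the bound of 0.1 set for this, so the numbers were taken to pair the arrays. Deviations within a genotype cancel out, so high correlations for equal numbers lower the others, and the contrast is not independent evidence. This pairing comes from the values, since the labels do not say what a number stands for. A fit with the replicate number as a block is given beside results that it changes. Its calls and p rest on a block chosen from these same values and may be too favourable.

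The procedure was tested on simulated arrays built from the real means and spreads, with 200 of the probe sets changed. Among those that passed the filter, it called 22.4% of those changed by 1.25-fold, 67.3% at 1.5-fold, 87.8% at 2-fold and 97.9% at 4-fold, with 4 false calls among 137 over 11261 probe sets. Simulated arrays without changes gave 0 calls. The simulation drew each probe set independently and without pairing of arrays. In the real data 1985 probe sets had a limma p under 0.05 before adjustment, so these rates may not hold for them. Alternatives covered the filter, normalization, pseudocount, variance model, array weights, replicate block, threshold, choice of probe set, inter-gene correlation and the omission of each array. No sample was left out.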

Results

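Sxl is the switch gene of female development in Drosophila. The study asked what its loss does to gene expression in the male head. The deletion had been crossed repeatedly into the Oregon-R wild-type strain, and the eye colour gene carmine (cm) and the wing gene cut (ct) marked its flanks. Deletion males therefore also carried mutant cm and ct, and their wild-type brothers came from the same kind of cross. Differences between the genotypes thus cannot be assigned to the loss of Sxl alone. Each genotype was measured on 3 arrays. Correlations between arrays were from 0.994 to 0.998 on the log2 scale.

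Sxl transcript signal was close to the lowest intensities of the arrays in the deletion males. Its 3 probe sets fell from 97.8 ± 7.76, 155 ± 9.54 and 190 ± 26.6 (mean intensity ± SD, n = 3 arrays) in wild type to 4.65 ± 0.646, 6.19 ± 0.0617 and 5.10 ± 1.04, which are log2 fold changes of -4.13, -4.44 and -4.97 with a limma adjusted p of at most 3.94e-07. The array labels therefore match the genotypes. The flanking marker cm, which encodes a subunit of a vesicle adaptor complex needed for eye pigment, fell from 60.3 ± 2.98 to 24.8 ± 3.23, a log2 fold change of -1.25 ± 0.11 (SE). The other marker, ct, had log2 fold changes of 0.23, 0.03 and -0.16 on its 3 probe sets, none past the threshold.

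**Figure D1:**
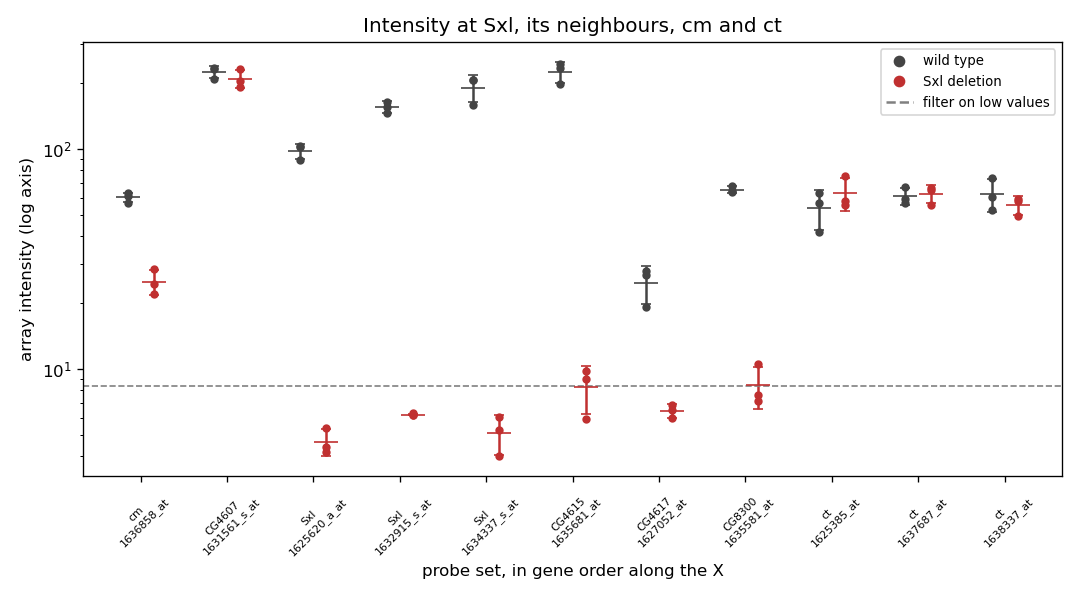
Intensity (log axis) of each array for the probe sets of cm, Sxl, ct and 4 neighbours of Sxl, in gene order along the X, with the mean (bar) and SD (whisker) of 3 wild-type arrays in grey and 3 deletion arrays in red; the dashed line is the filter on low values, an intensity of 8.35. Sxl and CG4617 lie below the line on every deletion array, CG4615 and CG8300 lie around it, and CG4607 and ct have similar values in both genotypes.

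Neighbours of Sxl fell with it. CG4615, CG4617 and CG8300, which lie 3, 4 and 5 genes from Sxl towards ct, fell from 224 ± 24.0 to 8.22 ± 2.02, from 24.5 ± 4.72 to 6.43 ± 0.455 and from 65.2 ± 2.37 to 8.40 ± 1.81, with log2 fold changes of -4.63, -1.76 and -2.83. CG4607, the next gene on the side of cm, had a log2 fold change of -0.10 and no call. Elsewhere between cm and ct, CG32726 fell (-0.80) and CG4593 (0.54), CG42246 (0.38) and CG2059 (0.34) rose. Without the intensity trend CG32726 kept its call and the 3 rises lost theirs. Of the 61 genes from cm to ct, 21 were tested with 28 probe sets, and 11 probe sets of 9 genes were called, 3 higher and 8 lower. That is 39.3% of the interval's probe sets, against 4.32% of the rest of the X (odds ratio 14.3, Fisher's exact p = 2.25e-08) and 2.14% of the autosomes (odds ratio 29.5, p = 9.29e-12). With the replicate block the other shares were 9.02% and 7.14% and the odds ratios 6.51 and 8.41. Sxl, cm and ct differ by the design of the cross, and without them 7 of 21 probe sets were called, with an odds ratio of 11.0 against the rest of the X (Fisher's exact p = 2.62e-05), or 5.04 with the block (Fisher's exact p = 0.00203). Without CG4615, CG4617 and CG8300 as well, a choice made after the data were seen, 4 of 18 were called, with an odds ratio of 6.31 (Fisher's exact p = 0.00726), or 2.88 with the block (Fisher's exact p = 0.0751). The mean log2 fold change of the interval's genes was -0.70 (median -0.10, camera p = 0.00329, p = 0.042 with an estimated correlation). With the block this last p was 0.177. Without Sxl, cm and ct the mean was -0.47, and without CG4615, CG4617 and CG8300 as well it was 0.05, neither past the threshold with camera.

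Outside the interval, the changes were many and mostly small. CG9377, an autosomal gene, rose from 240 ± 84.8 to 1057 ± 178 (log2 fold change 2.17 ± 0.22 SE, adjusted p = 0.00406), and Drosomycin (Drs), an antifungal peptide gene, rose from 495 ± 112 to 2199 ± 983 (2.08 ± 0.28, adjusted p = 0.0128). Among the other large rises were Smr, a transcriptional corepressor (1.16), shf, a Hedgehog pathway factor (0.95), the odorant-binding protein gene Obp8a (0.92), the immune-induced BomBc3 (0.90) and Cpn, a calcium-binding protein of photoreceptors (0.85). CG32683 (1.03), CG9689 (0.95), Osi8 (0.86) and CG9616 (0.85) completed the rises, apart from CG1637 below. Apart from CG1637, none of the genes named so far in this paragraph had another tested probe set that could have contradicted its rise. Large falls outside the interval were seen in CG15199 (-1.52), the glycosyltransferase gene Ugt37A3 (-1.26), CARPB (-1.14), rost, a gene of myoblast fusion (-1.11), CG1628 (-1.07) and the lipase gene Lip2, from 55.3 to 27.0. Among these largest changes the probe sets of 2 further genes disagreed. For CG1637 the brightest probe set fell (-0.36, adjusted p = 0.0253), another rose by 1.39 and the last had 0.19 (adjusted p = 0.131). For IP3K2 the brightest had -0.24 (adjusted p = 0.231, 0.0306 with the block), another fell by 1.21 and the last, at low intensity, had -0.06. Many of these genes lie on the X: shf is 37 genes from Sxl on the cm side, and Obp8a, CARPB, CG9689, CG32683, CG1628, CG1637 and CG15199 are 255 to 460 genes away on the ct side, with Smr and IP3K2 beyond them.

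Altogether 293 of 11261 probe sets passed the threshold, 138 higher and 155 lower in the deletion males, and 252 of them named 1 gene each, 245 genes in all. The median size of a called change was 1.38-fold, and 22 changes exceeded 2-fold, 7 higher and 15 lower. Of the 22, 4 have no single gene name in the annotation used here and were not placed on a chromosome: 2 fell, from 440 to 51.0 and from 42.1 to 4.89, more than any named gene outside the interval, and 2 rose, with log2 fold changes of 1.61 and 1.14. All 293 had 3 values beyond the other genotype's 3, as had 24.0% of all tested probe sets where chance gives 10%. With the replicate block 833 probe sets were called, 385 higher and 448 lower, and all 293 were among them. The count was 572 with array weights and 128 without the intensity trend, where 21 of the 53 named genes called here lost the call, Cpn, fit and RpL17 among them. The count fell to 85, 54 and 61 without deletion replicate 1, 2 or 3 and to 110 and 157 without wild-type replicate 2 or 3, and rose to 432 without wild-type replicate 1.

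The genes of phototransduction, the light response of the eye, were higher in the deletion males. Of 26 members 23 had a positive log2 fold change (median 0.28, camera adjusted p = 1.16e-09), but adjusted p = 0.683 with an estimated correlation. Rises past the threshold were seen in Gbeta76C, the photoreceptor G protein subunit (0.38), the signalling scaffold inaD (0.53), the diacylglycerol kinase rdgA (0.57) and prom (0.62), 4 genes in all, 11 with the replicate block and 17 adjusted over the list alone. Without the intensity trend all 4 lost the call on these probe sets. rdgA lies on the X, 209 genes from Sxl on the ct side, and its other probe sets had 0.71 (adjusted p = 0.0285), 0.73 (adjusted p = 0.0896, 0.0227 with the block) and, at low intensity, -0.08. The channel gene trp had 0.55 (adjusted p = 0.0621, 0.0217 with the block). By contrast retinin, an abundant eye gene not known for a part in the light response, had -0.0048. The mean of the list was 0.29 and was 0.19 without wild-type replicate 1.

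Immune genes had a positive shift that rested on few members. Drs was the 1 member of 25 called over all probe sets, against 4 with the block and 3 adjusted over the list alone, and 18 were positive (median 0.10, mean 0.37, camera adjusted p = 0.00951, adjusted p = 0.683 with an estimated correlation). BomS2 (0.29, adjusted p = 0.0544, 0.0167 with the block) and the peptidoglycan-binding PGRP-SB1 (0.91, adjusted p = 0.0982, 0.0303 with the block) were next. Without wild-type replicate 3 the list's mean was 0.16 (adjusted p = 0.257).

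Genes of a mixed list on starvation and insulin, called the insulin list here, were mostly lower. Of 25 members 20 had a negative log2 fold change (median -0.18, camera adjusted p = 1.55e-05), but adjusted p = 0.183 with an estimated correlation. Falls past the threshold were seen in 6: the insulin-like peptide genes Ilp2 (-0.36) and Ilp5 (-0.47), the insulin-binding ImpL2 (-0.54), the acetyl-CoA synthetase AcCoAS (-0.36), the lipid droplet gene Lsd-2 (-0.36) and the insulin target tobi (-0.92). The count was 10 with the block and 10 adjusted over the list alone. Without the intensity trend Ilp2, ImpL2 and tobi lost the call, while AcCoAS and Lsd-2 kept it. Ilp5 was not followed across the alternatives. Of 15 head fat body and hemolymph genes 9 were negative and 6 positive, and the list did not pass (median -0.13, camera adjusted p = 0.0672). With the block its adjusted p was 0.0355, but p = 0.221 with an estimated correlation. Its members tobi, which is in both lists, and Obp99b (-0.91) fell, and with the block 4 members were called. Respiratory chain genes had a small negative shift, with 48 of 62 below 0 (median -0.06, camera adjusted p = 0.00066, adjusted p = 0.683 with an estimated correlation). None was called with limma over all probe sets or over the list alone, and 1 was with the block. With fry, which tests whether the members of a list move one way on balance and does not compare them with other genes, the insulin list passed (adjusted p = 0.017), and phototransduction (0.186), the respiratory chain (0.188) and immunity (0.37) did not.

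**Figure D2:**
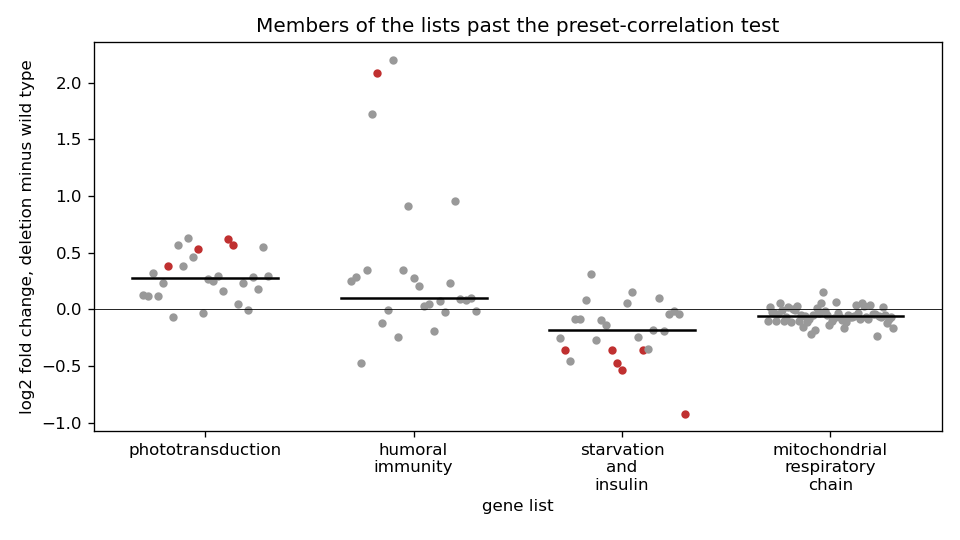
Log2 fold change (deletion minus wild type) of each tested member of the 4 lists past the camera test at a preset correlation, 1 point per gene in alphabetical order, red where adjusted p is under 0.05, with the list's median as a line. The medians are 0.28, 0.10, -0.18 and -0.06, and the immune list has a few members far above its median.

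The sex determination genes downstream of Sxl in females showed no call. The log2 fold changes were -0.08 for tra, 0.00 for tra2, 0.01 for dsx and 0.27 for fru. These are intensities of single probe sets, and splicing and protein were not assessed. Of 16 list members 2 fell, fit (-0.62) and Obp99b, both genes of the head fat body with sex-biased expression, and the list did not pass (camera adjusted p = 0.35). Of 11 dosage compensation genes none was called by limma (camera adjusted p = 0.206), msl-2 had 0.04, and Su(var)3-7 had -0.45 (adjusted p = 0.0768, 0.0349 with the block). X-linked genes did not shift as a group. Their median was 0.02 against 0.00 on the autosomes (1426 X-linked genes, camera p = 0.287, p = 0.508 with an estimated correlation). Calls were nevertheless more frequent on the X outside the interval than on the autosomes, 69 of 1597 probe sets against 172 of 8041 (odds ratio 2.07, Fisher's exact p = 2.47e-06). With the block they were 144 and 574 (odds ratio 1.29, Fisher's exact p = 0.0105). Away from the stretch from 100 genes on the cm side to 500 on the ct side, limits chosen after the positions were seen, 25 of 1220 probe sets were called (2.05%), 77 with the block.

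**Figure D3:**
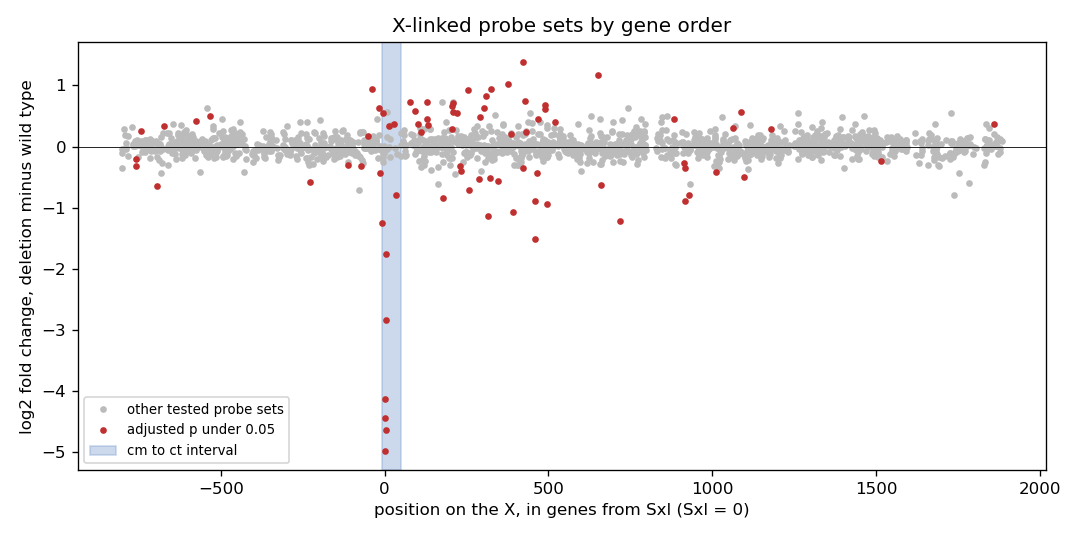
Log2 fold change (deletion minus wild type) of tested X-linked probe sets against position on the X, counted in genes from Sxl, with called probe sets in red and the cm to ct interval shaded. Outside the interval, called probe sets within 100 genes of Sxl are 2 of 24 on the ct side and 5 of 53 on the cm side, and from there to 500 genes 37 of 300 and 2 of 231 (57 and 10 with the block), limits chosen after the positions were seen.

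Other lists did not pass camera at the preset correlation, though single members changed; the adjusted p after a list is the list's. In the clock list the neuropeptide gene Pdf fell (-0.57) and Clk rose (0.57), while per (0.28) and tim (0.02) were not called (list adjusted p = 0.731). In the eye pigment list se (0.61) and cl (0.25) rose and cm fell, 3 in all and 5 with the block (list adjusted p = 0.326). Among odorant-binding protein genes Obp8a and Obp56e (0.42) rose and Obp44a (-0.19) and Obp99b fell, 4 in all (list adjusted p = 0.206), and with the block 12 of 30 changed, 7 higher and 5 lower. Cyp4ae1 (0.49) rose and Cyp4s3 (-0.79) fell among cytochromes P450 (0.206), and with the block 3 were higher and 11 lower. Desat1 (-0.32) fell in the courtship list (0.731), E(spl)mbeta-HLH (0.41) rose in the Notch list (0.35), RpL17 (0.17) rose among ribosomal protein genes (0.868), and Ugt37A3 fell among glycosyltransferases (0.206). With the block the courtship, Notch and glycosyltransferase lists had 2 called members each. In the cuticle list TwdlG fell from 92.9 to 46.0 and Cpr73D (0.55) rose, 2 in all and 8 with the block. The list's adjusted p of 0.0672 was 0.0355 with the block, but p = 0.0776 with an estimated correlation. Hedgehog (0.531), heat shock (0.731), glutathione transferase (0.86), chemoreceptor (0.731) and proteasome (0.0858) lists had no called member with limma, but with the block 4 glutathione transferase genes were called, 1 higher and 3 lower. The Hedgehog list does not hold shf, the pathway factor that rose (0.95).

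Markers of other cells gave little. Neither glial genes (13 tested, camera adjusted p = 0.206) nor synaptic genes (28 tested, 0.387) passed, with the X-linked dlg1 (0.61) called among the latter. Its other probe sets had 0.68 (adjusted p = 0.0295), 0.04 and -0.09. With the block 2 glial genes were lower and 2 synaptic genes higher. Muscle (21 tested, 0.711), gut (15, 0.759) and testis (6, 0.116) markers had no call with limma, and 1 gut gene was higher with the block. The yolk and female-biased (4), male accessory gland (2) and salivary gland (4) lists had too few measured members for the test. Their called members were fit and Obp99b, both in the first list. All arrays were from males, so membership of that list does not show that Obp99b is female-biased. The ratio of 3' to 5' signal, a sign of RNA integrity, was 4.88 ± 0.284 in wild type and 4.30 ± 0.432 in deletion males for Act5C (n = 3, exact permutation p = 0.2), 3.67 ± 0.106 and 3.81 ± 0.107 for GAPDH (exact p = 0.3) and 3.79 ± 0.269 and 3.40 ± 0.093 for eIF4a (exact p = 0.1, the smallest that 3 against 3 arrays allow). These tests ignore the pairing. In every pair of equal number the deletion array had the lower ratio for Act5C and eIF4a, but not for GAPDH.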

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

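The omission of both arrays numbered 1 and of the 6 genes around Sxl was chosen after the data were examined, and the other alternatives before. The cause of a change below was not tested unless the alternative itself removes probe sets, genes or arrays.

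The count of 293 changed probe sets was 128 without the intensity trend (55 higher, 73 lower), 572 with array weights (255 and 317), 833 with the replicate block (385 and 448), 451 without both arrays numbered 1 (211 and 240) and 683 at a threshold of 0.1 (304 and 379). Leaving out single arrays gave 54 to 432 (17 to 200 higher, 37 to 232 lower), with the lowest count without deletion replicate 2 and the highest without wild-type replicate 1. The block added calls for 20 named genes and 2 lists and removed none. The filter, normalization, pseudocount and robust settings kept between 88.4% and 99.0% of the 293.

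In the cm to ct interval 4 of the 11 calls were left with the filter at the 60th percentile, 7 without Sxl, cm and ct, 4 without the 6 genes, and 7 to 11 with single arrays left out. The mean log2 fold change was -0.51 with that filter and -0.47 without Sxl, cm and ct, neither past the threshold with camera. Without the 6 genes it changed sign to 0.053, not past the threshold, since the genes that fell most had been removed.

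Of the 4 lists none passed with an estimated correlation: means of 0.29, 0.37 and -0.054 for phototransduction, immunity and the respiratory chain with adjusted p = 0.683, and -0.19 for the insulin list with adjusted p = 0.183, 0 lists in all. With single arrays left out 3 to 9 lists passed, 9 without wild-type replicate 1, and the mean of the immune list was 0.16 to 0.58 and failed without wild-type replicate 3.

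Of 53 named genes called, 23 kept the call under every alternative that tested them (6 of these were removed by the filter at the 60th percentile), 7 lost it with single arrays left out and under no other, and 23 lost it under others, 21 of them without the intensity trend. No called gene changed sign. Sxl kept its call wherever it was tested, but signal near background limits how large its fold can be measured. Values as deposited were already the main setting, so that alternative gave no separate value.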

Other observations

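All tests in this part were chosen after the values they concern had been seen, and some limits on what would count were reworded after a first result.

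Neuropeptide genes, a list put together after single members had been seen to fall, tended to be lower. Among 24 tested, 18 had a negative log2 fold change (median -0.11), 5 fell past the threshold and 0 rose: Pdf (-0.57), Ilp2 (-0.36), Ilp5 (-0.47), Dh44 (-0.32) and sNPF (-0.37). Of the 24 genes 3 are also in the insulin list. That neuropeptide transcripts may be lower as a group is a hypothesis that the data leave open. Camera gave p = 0.0001042 at the preset correlation but 0.0999 with an estimated one. Of the 10 splits of the 6 arrays, 2 gave as small a value of the latter, the real one included. With the block 7 neuropeptide genes were called lower, and the camera p were 0.0002098 and 0.2231. On chromosome 4, 7 of 79 probe sets were called, against 2.07% on the large autosomal arms (Fisher's exact p = 0.00144), and with the block 15 against 7.02% (Fisher's exact p = 0.000396). Of these 79, 66 were lower in the deletion males, but another split of the arrays put 68 on the same side. Of the called probe sets 41 have no single gene name in the annotation used here and stay unnamed, 4 changes over 2-fold among them.

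With 3 arrays of each genotype, 3 against 3 give 10 splits, too few for a share under 0.05. The real split gave 293 changed probe sets and the highest other 0, which made it 1 of 10. It gave 11 calls in the interval and the highest other 0, which follows from the 0 calls of every other split and adds nothing to it. In the other splits the genotype difference itself widens the residual spread, so their low counts are partly built in. For lists the real split gave 4 and the highest other 9, with 7 of 10 giving as many. Among the 4 splits that part all 3 pairs of equal number, the real one included, the highest other gave 0 probe sets and 4 lists, and the splits that keep a pair together gave 2 to 9 lists. Phototransduction had its smallest camera p in the real split (4.48e-11 against 1.65e-07), as had the insulin list (1.2e-06 against 0.00129), while 2 splits for the respiratory chain and 4 for immunity were as extreme, the real one included.

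On the X outside the interval, calls within 100 genes of Sxl were 5 of 53 probe sets on the cm side and 2 of 24 on the ct side, and from there to 500 genes they were 2 of 231 and 37 of 300 (10 and 57 with the block). These limits were drawn after the positions had been seen, so no p is given for them. A segment of the original chromosome that stayed linked to the deletion is a candidate explanation. The test run for it was the median distance of calls from Sxl (392 genes, 641 for all X-linked probe sets tested). That distance was matched in a share of 0.2085 of circular shifts of the calls along the X. The test pooled both sides, whereas calls from 100 to 500 genes away lay mostly on the ct side. It therefore neither excludes a linked segment nor bears it out. Variants under single probe sets could also change signal there: a second probe set moved alike in 2 of 6 called genes that lie 209 to 496 genes from Sxl and in 12 of 21 autosomal ones (Fisher's exact p = 0.3845), too few to decide. An effect of Sxl itself on these genes was not tested and stays open.

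CG4615, CG4617 and CG8300 may lie within the deletion. If so they should be at background in the deletion males. The highest of their means there was 8.40, within 1 SD of the filter's 8.35, while the lowest single wild-type array had 19.1. The filter is a chosen percentile and not a measured background. Their means in the deletion males, 6.43 to 8.40, all lay above those of the deleted Sxl, 4.65 to 6.19. The test therefore does not decide whether they were deleted. Loss of expression without loss of the genes would look alike on these arrays, and the values had been seen before the test was set.

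The higher phototransduction genes were not the work of wild-type replicate 1 alone, since the mean without it was 0.1929 against 0.2887. Nor were they due to X-linked members alone, but this test had little room to find otherwise. Only 3 members are X-linked, with a mean of 0.1935, and the 23 off the X had a mean of 0.3011. A larger share of eye tissue in the deletion heads stays open. It would raise eye genes alike, and 12 genes of the eye at or below an intensity of 5000 ranged from 0.16 to 0.63. The simulated probability of as much heterogeneity was 0.166 for these, against 0.00036 for all 15. The other 3, bright genes, rose less and may be near saturation, which was not tested. The simulation drew genes independently, whereas the phototransduction list had an estimated inter-gene correlation of 0.59. Shared error makes genes scatter less, so 0.166 may be too high and does not decide the question. A chi-square form of that test, run first, gave 0.0378 for the 12, but it takes the standard errors as known, which 3 arrays per genotype do not allow. An effect of the Sxl deletion on eye gene expression was not separated from a larger share of eye tissue. Nor was an effect of mutant cm or ct, which the deletion males also carried, or of the low signal of CG4615, CG4617 and CG8300. A linked segment of the X, if it stayed, could also contribute. The design cannot tell these apart, for the eye genes or for the other changes.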
